A study of Mus musculus with 60 samples.

How the data were processed

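Immortalised mouse ear fibroblasts were grown overnight at 37 °C and moved to 24, 34, 37 or 40 °C. After 2 h of adaptation, total RNA was taken from unstimulated cells (0 h). The other cells received TNF-α or IL-1β at 10 ng/mL for 1 or 3 h. This gives 5 conditions at each of 4 temperatures, 20 groups of 3 biological replicates and 60 libraries, of which 48 were stimulated and 12 were not. Unstimulated cells had therefore spent 2 h at their temperature, and stimulated cells 3 or 5 h. A response compares cells that also differ in those hours, since no unstimulated group was kept for 1 or 3 h longer. The 24 °C libraries carry the numbers 46 to 60 and the other temperatures 1 to 45. The labels do not state whether these were made apart. If they were, that cannot be told apart from 24 °C in any comparison with 37 °C.

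The authors deposited 1 table of expression values in FPKM, with 10122 genes and 60 libraries. The submitters' notes name STAR 2.7.11b, RSEM 1.3.3, edgeR and the mouse assembly GRCm39, without giving the order or the role of each step. All 10122 gene identifiers, with their version numbers, are those of GENCODE M21, and 10118 of the symbols are equal. The notes and the identifiers thus point to different annotations, and no coordinates are given here. Every gene in the table reaches an FPKM of at least 1 in at least 4 libraries, which is a property of the deposited table. A symbol that is shared by several identifiers (Gm4430) was kept under its identifiers. Rela and Nfkb2 are not analysed here. Of all values, 3.77% are 0.

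The table holds no read counts, so depth was estimated from the steps in which low FPKM values rise. For 373 genes, chosen because their low values clustered, the smallest values lay near whole multiples of a common step. Of 3518 values at 2 or 3 steps, 85.7% lay within 0.15 of a whole number. The relative depths were set to bring such values near whole numbers, so this share is no independent check. Step sizes of 239 of 307 genes with a single transcript followed their length within 3%, on a line that was chosen to hold many genes. The estimate is 3.53 to 7.66 M (mega) mapped fragments per library, with a geometric mean of 5.83 M. An FPKM of 1 in a transcript of 1 kb then rests on about 5.83 fragments. Values of a few FPKM are coarse for that reason. The 24 °C libraries were the shallowest, at 4.53 ± 0.48 M (mean ± SD, n = 15), against 6.61 ± 0.58 at 34 °C, 6.27 ± 0.54 at 37 °C and 6.30 ± 0.73 at 40 °C. Between replicates of a group, Pearson r across genes on the log2 scale was 0.969 to 0.983 over 60 pairs.

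Values were analysed as log2(FPKM + 1). A gene had to reach an FPKM of 1 in at least 3 libraries, which removed 0 of 10122 genes. A linear model with 1 mean per group was fitted across all 60 libraries in limma 3.58.1 (R 4.3.3), with moderated variances and a mean-variance trend (40 residual and 4.37 prior degrees of freedom). Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. The 33 comparisons are 3 of unstimulated cells (24, 34 and 40 °C against 37 °C) and 16 responses, each against unstimulated cells of the same temperature. There are also 12 differences between the response at 24, 34 or 40 °C and that at 37 °C (interaction terms), and 2 of TNF-α against IL-1β averaged over the 4 temperatures. For interaction terms, a larger or smaller response means a positive or negative term. A fall that is weaker than at 37 °C thus counts as larger, and a stronger fall as smaller. Log2 changes carry the standard error of the model (SE). Levels are means ± SD of 3 libraries in FPKM unless another n is given.

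Before the data were examined, the groups, the comparisons, the test, its threshold, the rule for naming genes, the gene lists and the alternatives below were set. Named genes are the 6 largest rises and 6 largest falls among called genes with replicates that do not overlap, for each temperature and each 37 °C response. The rule adds up to 4 called members of each list with the largest change, the 3 largest positive and negative interaction terms and the 4 genes that stood highest with each cytokine. Rela, Relb, Rel, Nfkb1, Nfkb2, Nfkbia, Tnfaip3, Cxcl1, Ccl2, Il6, Cirbp, Rbm3, Hspa1a and Hspa1b were to be named whatever their values. Unnamed gene models were counted and not named.

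The 21 lists hold 371 genes, 254 of them measured. They are NF-κB subunits (3 of 5 measured), NF-κB inhibitors and feedback genes (11 of 15), TNF and IL-1 receptor signalling (21 of 22), chemokines (15 of 21), cytokines and colony-stimulating factors (9 of 18), and adhesion and inflammatory effectors (10 of 20). Others are immediate-early genes (20 of 31), interferon-stimulated genes (15 of 33), heat shock genes (22 of 25), cold-inducible RNA-binding proteins (2 of 3), the circadian clock (15 of 20), and unfolded protein and integrated stress responses (20 of 26). Metabolic and structural lists are cholesterol synthesis (17 of 22), hypoxia and glycolysis (13 of 20), cell cycle (24 of 25), extracellular matrix and fibroblast identity (15 of 22) and mitochondrially encoded genes (15 of 15). Marker lists of other cells are keratinocyte (1 of 8), leukocyte (2 of 8), endothelial (1 of 6) and chondrocyte (3 of 6). For each list described, the called members are counted, and also the number called when p values were adjusted over the list alone. The 17 lists that could be tested as a whole went through camera in limma with a preset correlation of 0.01. The 561 p values were adjusted together, and the test was repeated with a correlation estimated for each list.

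The procedure was tested on simulated data with the spread of these libraries. In the comparison of 24 with 37 °C it recovered 27 of 53 genes changed 1.5-fold (50.9%), 63 of 79 changed 2-fold (79.7%) and 67 of 68 changed 4-fold (98.5%), with 4 false calls. For the interaction of TNF-α at 3 h with 24 °C it recovered 29 of 63 (46.0%), 45 of 71 (63.4%) and 61 of 66 (92.4%), with 5 false calls. A count of called genes thus misses many changes below 2-fold.

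Alternatives were a pseudocount of 0.1, rescaling of each library by its median ratio to the geometric mean over libraries (factors 0.959 to 1.04), no filter on low values, the replicate number as a block, and leaving out each library of the compared groups in turn. A filter on a mean FPKM of at least 1 and a model of the 34, 37 and 40 °C libraries alone were added after the values were seen. Other splits of the compared libraries were also counted, up to 100 per comparison. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the description of the table and for figures. No file was left out. Sequence reads were not used here.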

Results

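The 60 libraries looked like fibroblasts throughout. Col1a1, which encodes a chain of type I collagen, stood at a mean of 1077 FPKM over all libraries (843 to 1732), Col1a2 at 1133 and Vim, an intermediate filament of mesenchymal cells, at 2362 (1913 to 2929). Markers of other cells were low: the keratin Krt10 at 1.27 FPKM (0 to 4.13), the macrophage genes Cd68 at 1.01 (0 to 2.93) and Lyz2 at 2.64 (0.87 to 4.6), and the endothelial gene Vwf at 0.426 (0.05 to 2.5). Of the chondrocyte list, Sox9 stood at 10.7 FPKM (5.23 to 18.1), Comp at 6.00 (3.48 to 8.6) and Col9a1 at 0.599 (0 to 1.55). The first principal component held 18.4% of the variance and set 24 °C (scores 21.9 to 30.6) apart from the other temperatures (-22.2 to 3.00).

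At 24 °C, unstimulated fibroblasts held more mRNA of immediate-early genes and of some inflammatory genes, and less of several matrix genes, than at 37 °C. Egr1, a transcription factor induced within minutes of a stimulus, stood at 184 ± 24.8 FPKM against 49.9 ± 28.5 (log2 change 2.08, SE 0.30, adjusted p = 1.5e-06). The stress factor Atf3 stood at 10.2 ± 2.74 against 2.06 ± 0.193 (1.84, SE 0.20), and Bhlhe40, a repressor of the circadian clock, at 72.5 ± 4.56 against 23.9 ± 1.41 (1.56, SE 0.12). The chemokine genes Cxcl1 and Ccl2, which recruit neutrophils and monocytes, were higher before any cytokine was given: Cxcl1 at 30 ± 6.05 against 9.65 ± 5.26 FPKM (1.68) and Ccl2 at 51.6 ± 9.85 against 25.2 ± 6.94 (1.02). Ptgs2, which makes prostaglandins, stood at 81 ± 13.4 against 29.5 ± 7 (1.44). Cemip, a hyaluronan-degrading enzyme, fell by 1.91 on the log2 scale (2.03 ± 0.241 against 10.4 ± 1.14 FPKM) and Aldh1a7 by 2.05, and the small matrix proteoglycan genes Ogn (-1.75, SE 0.23) and Aspn (-1.66) also fell. The fibrillar collagen gene Col3a1 stood at 135 ± 11.7 against 213 ± 17.5 FPKM (-0.65, SE 0.09).

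In that comparison limma called 2098 of 10122 genes, 956 higher and 1142 lower at 24 °C (1095 and 1021 after rescaling), 175 of them by at least 2-fold. Of 20 measured immediate-early genes, 17 were higher and 1 lower (18 and 1 adjusted over the list alone), Dusp4 (1.62, SE 0.19) and Fos (1.66, SE 0.35) among them (camera adjusted p = 8.6e-18; 6e-05 with an estimated correlation). Cell cycle genes were higher in 15 of 24 cases and lower in 0 (17 and 0 adjusted over the list alone), such as the mitotic kinase Plk1 at 73.5 ± 3.81 against 42.7 ± 3.46 FPKM (0.77) and Birc5 (0.65). Their list had an adjusted p of 2.8e-08 with the preset correlation, and adjusted p = 0.105 with an estimated correlation. Heat shock genes were higher in 12 of 22 cases and lower in 1 (13 and 1 adjusted over the list alone), with the co-chaperone Fkbp4 at 0.62 and Hsp90aa1 at 0.57, and Hsf2 at -0.44 (adjusted p = 1.2e-05; adjusted p = 0.0472 with an estimated correlation). Of 15 matrix genes, 2 were higher and 4 lower (2 and 6 adjusted over the list alone; adjusted p = 0.16). Of the 3 chondrocyte genes, Sox9 (1.02, SE 0.15) and Col9a1 (0.63) were higher (2 adjusted over the list alone). The 24 °C libraries were also the shallowest and carry a run of numbers of their own. If they were made apart from the others, which the labels do not state, that cannot be told apart from the temperature.

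Inflammatory lists went both ways at 24 °C. Chemokine genes were higher in 2 of 15 cases and lower in 1 (2 and 1 adjusted over the list alone). Cytokine genes were higher in 1 of 9 cases (1 adjusted over the list alone), and adhesion and effector genes higher in 2 of 10 and lower in 2 (2 and 4 adjusted over the list alone). Lower were Ccl9 (-1.07; not called without 24 °C unstimulated replicate 1, -0.47, or 37 °C unstimulated replicate 2, -0.94) and Lcn2 (-1.15; not called without 24 °C unstimulated replicate 1, -0.97). The complement gene C3 was also lower (-0.57; not called without any 1 of the 6 libraries but 37 °C unstimulated replicate 3, -0.64 to -0.50). Clock genes were higher in 3 of 15 cases and lower in 3 (6 and 4 adjusted over the list alone), with Nr1d1, a clock repressor, at 1.06. Receptor signalling genes were higher in 1 of 21 cases and lower in 5 (1 and 5 adjusted over the list alone). The NF-κB feedback gene Tnfaip3, a deubiquitinase that limits the pathway, rose by 0.63 (SE 0.11), while the subunits Rel (-0.20, adjusted p = 0.123), Relb (-0.02) and Nfkb1 (0.04) and the inhibitor Nfkbia (0.09) were not called. Among unfolded protein response genes 3 of 20 were higher, such as Ppp1r15a (1.09) and the chaperone Calr (0.46), and 3 lower (3 and 4 adjusted over the list alone). Cholesterol synthesis genes were higher in 3 of 17 cases, and Sc5d was lower (-0.66; 4 and 2 adjusted over the list alone). Of 15 mitochondrially encoded genes, 5 were higher (5 adjusted over the list alone; adjusted p = 0.0121; adjusted p = 0.463 with an estimated correlation), a pattern treated in the closing section. The cold-inducible gene Rbm3, which encodes an RNA-binding protein, was not raised at 24 °C: it stood at 296 ± 42 against 425 ± 8.4 FPKM (-0.53, SE 0.11, adjusted p = 0.00049), and Cirbp at 13.4 ± 2.49 against 19.2 ± 5.27 (-0.47, adjusted p = 0.149). Adjusted over the list alone, both were lower.

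At 34 °C, unstimulated cells differed from 37 °C in few genes, several of them immediate-early or stress-response genes. Egr1 stood at 10.2 ± 0.643 against 49.9 ± 28.5 FPKM (-1.96, SE 0.30, adjusted p = 0.00019), and Btg2, an antiproliferative gene, at 12.9 ± 1.24 against 33.5 ± 11.6 (-1.25, SE 0.15). Zfp36, which directs decay of inflammatory mRNAs, was lower as well (4.5 ± 0.31 against 11.5 ± 2.85 FPKM, -1.15), as was Arc (-1.22). Atf3 (1.33, SE 0.20) and Chac1, a target of the integrated stress response (33.7 ± 3.54 against 13.4 ± 1.88 FPKM, 1.27), were higher. Limma called 37 genes, 19 higher and 18 lower, 10 by at least 2-fold. The count was 21 without 34 °C unstimulated replicate 1, 21 without 37 °C unstimulated replicate 1, 16 without 34 °C unstimulated replicate 2 and 14 without 37 °C unstimulated replicate 3. Immediate-early genes were higher in 2 of 20 cases and lower in 5 (3 and 8 adjusted over the list alone; adjusted p = 4.7e-05, and adjusted p = 0.059 with an estimated correlation). Unfolded protein response genes were higher in 4 of 20 cases (6 adjusted over the list alone; adjusted p = 1.9e-09; 0.00378 with an estimated correlation). Single calls of stress genes were fragile. Those of Trib3 (0.96 to 1.17) and Sesn2 (0.61 to 0.72) ended without any 1 of the compared libraries. That of Ddit3 (0.73 to 0.91) ended without any but 37 °C unstimulated replicate 2. Cirbp stood at 30.7 ± 4.04 FPKM (0.68, adjusted p = 0.379) and Rbm3 at 457 ± 43 (0.10), neither of them called.

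At 40 °C, 2 h were enough for a heat shock response. Hspa1b, an inducible chaperone of the Hsp70 family, stood at 207 ± 36.5 FPKM against 37 ± 2.19 at 37 °C (2.44, SE 0.12, adjusted p = 8.8e-20). The small heat shock gene Hspb1 stood at 701 ± 264 against 115 ± 6.74 (2.54, SE 0.19), Dnajb1 at 90.6 ± 22.6 against 22.1 ± 1.52 (1.96), and Hspa1a at 10.1 ± 2.62 against 1.34 ± 0.124 (2.22). Genes of the unfolded protein and integrated stress responses also rose: Herpud1 to 209 ± 48.3 from 51.6 ± 1.02 FPKM (1.97), the chaperone gene Hspa5 to 893 ± 228 from 282 ± 19.6 (1.63), and Ddit3 (1.41) and Manf (1.10). Egr1 was lower (9.32 ± 2.33 FPKM, -2.10, SE 0.30), as were Cirbp (8.35 ± 2.47 FPKM, -1.11, SE 0.23, adjusted p = 0.0014) and the chemokine gene Cxcl5 (-1.11).

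Limma called 419 genes at 40 °C, 217 higher and 202 lower, 42 by at least 2-fold; without 40 °C unstimulated replicate 3 the count was 242. Of 22 heat shock genes, 21 were higher and 0 lower (22 and 0 adjusted over the list alone; camera adjusted p = 2.1e-92; 1.2e-11 with an estimated correlation), Hspa4 (0.15, adjusted p = 0.174) being the exception over all genes. Unfolded protein response genes were higher in 13 of 20 cases and lower in 1 (13 and 1 adjusted over the list alone; adjusted p = 3.6e-28; 9.1e-07 with an estimated correlation). Immediate-early genes were higher in 1 of 20 cases and lower in 3, Klf2 (-0.77) among them (1 and 5 adjusted over the list alone; adjusted p = 0.0401, and adjusted p = 0.39 with an estimated correlation). In hypoxia and glycolysis genes P4ha1, a collagen-modifying enzyme, rose by 0.92 and Hk2, a hexokinase, fell by 0.82 (1 and 1 adjusted over the list alone). Rel (0.13, adjusted p = 0.582) and Rbm3 (-0.23, adjusted p = 0.309) were not called.

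**Figure D1:**
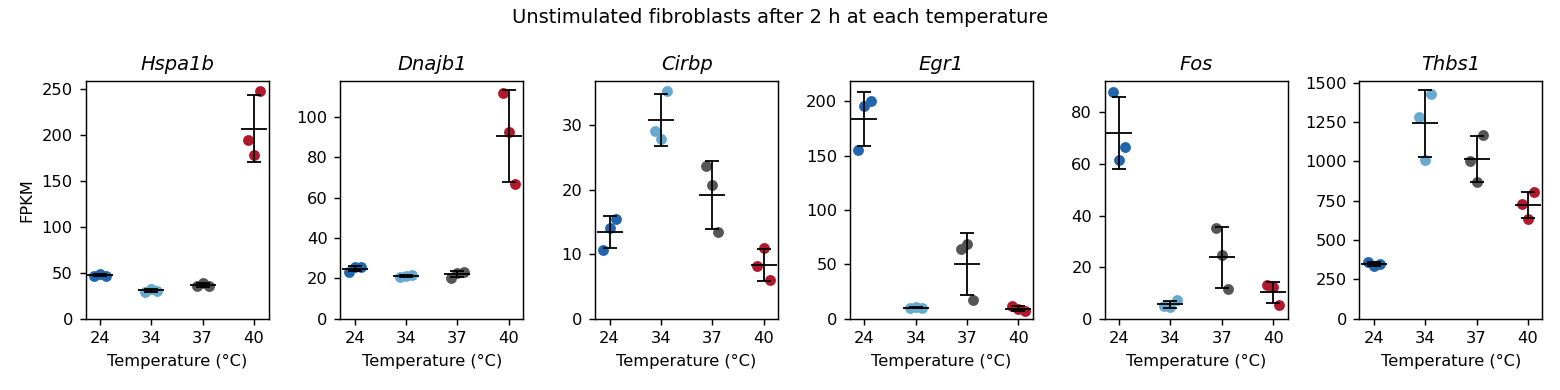
Levels in unstimulated fibroblasts after 2 h at 24, 34, 37 or 40 °C, in FPKM, with mean ± SD and 3 libraries per group. Hspa1b reached 207 ± 36.5 at 40 °C, and Egr1 reached 184 ± 24.8 at 24 °C and 9.32 ± 2.33 at 40 °C.

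TNF-α at 37 °C induced chemokine, feedback and NF-κB subunit genes within 1 h. Ccl2, a monocyte chemokine, rose by 5.40 on the log2 scale (SE 0.17, adjusted p = 1.1e-28), Tnfaip3 by 4.69 and the adhesion molecule gene Icam1 by 4.29 (from 0.94 ± 0.132 to 37.7 ± 9.61 FPKM). Nfkbia, which encodes the inhibitor that holds NF-κB in the cytoplasm, went from 30.8 ± 6.5 to 475 ± 13.9 FPKM (3.92, SE 0.13). Rel (ENSMUSG00000020275.9), the gene of the c-Rel subunit, went from 2.32 ± 0.181 to 9.73 ± 0.35 FPKM (1.69, SE 0.09), Relb rose by 2.33 and Nfkb1 by 0.73. Csf2, a growth factor gene for myeloid cells, was listed at 0 in unstimulated libraries and reached 18.8 ± 0.955 FPKM. Fos fell (-1.92, SE 0.35), from uneven unstimulated levels of 35.2, 24.7 and 11.6 FPKM to 4.37, 3.98 and 7.06 in replicates 1, 2 and 3. The hours at 37 °C also differ between these cells. Limma called 303 genes, 233 higher and 70 lower, 102 by at least 2-fold.

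Of 15 chemokine genes 11 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 8.1e-54; 1.4e-11 with an estimated correlation), and of 11 inhibitor and feedback genes 7 rose and 0 fell (7 and 0 adjusted over the list alone). All 3 measured subunit genes rose, with 5 of 9 cytokine genes and 6 of 10 adhesion and effector genes (3, 7 and 6 adjusted over the list alone). Immediate-early genes rose in 13 of 20 cases and fell in 2 (14 and 2 adjusted over the list alone), Atf3 by 3.25 among those that rose. Receptor signalling genes rose in 3 of 21 cases (4 adjusted over the list alone; adjusted p = 0.00871; adjusted p = 0.151 with an estimated correlation).

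By 3 h with TNF-α the response at 37 °C had broadened. Icam1 reached 123 ± 22.5 FPKM (5.98, SE 0.20), Ccl2 rose by 5.86 and Ccl5, a chemokine for T cells, went from 0.487 ± 0.454 to 34.6 ± 9.37 FPKM (4.60, SE 0.37). Gbp2, an interferon-induced GTPase gene, reached 18.4 ± 10.9 FPKM (3.70) and the adhesion gene Vcam1 rose by 3.05. Among subunits, Relb went from 4.74 ± 1.03 to 61.8 ± 6.27 FPKM (3.46, SE 0.13) and Nfkb1 from 27 ± 0.99 to 90.8 ± 14.3 (1.71, SE 0.11), while Rel stood at 4.37 ± 0.556 (0.69, SE 0.09). Fos (-2.91), the adrenergic receptor gene Adra1d (-2.21), the protease gene Adamts1 (-2.07), Irs2 (-1.78) and the growth factor receptor gene Pdgfrb (-1.06) fell.

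Limma called 1418 genes at 3 h, 663 higher and 755 lower (810 and 610 after rescaling of the libraries), 258 by at least 2-fold. Chemokine genes rose in 12 of 15 cases and fell in 1 (13 and 1 adjusted over the list alone; adjusted p = 1.6e-36; 8.6e-10 with an estimated correlation). Interferon-stimulated genes rose in 7 of 15 cases and fell in 1 (10 and 1 adjusted over the list alone; adjusted p = 7.1e-09; 0.000981 with an estimated correlation). Of 11 inhibitor genes 8 rose (8 adjusted over the list alone), and of 10 adhesion and effector genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; 8 and 0 after rescaling). Unfolded protein response genes rose in 6 of 20 cases (7 adjusted over the list alone; adjusted p = 0.000591; adjusted p = 0.116 with an estimated correlation). Cell cycle genes rose in 1 of 24 cases and fell in 5 (1 and 5 adjusted over the list alone; adjusted p = 0.149), and matrix genes rose in 1 of 15 and fell in 4 (3 and 4 adjusted over the list alone; adjusted p = 0.234), Col3a1 by 0.42 among those that fell.

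IL-1β at 37 °C also raised chemokine and feedback genes. After 1 h Cxcl1 went from 9.65 ± 5.26 to 542 ± 16.2 FPKM (5.83, SE 0.24, adjusted p = 7.9e-24), Ccl2 rose by 4.82 and Cxcl5 went from 4.99 ± 0.752 to 104 ± 15.9 FPKM (4.13, SE 0.23). Zc3h12a, an RNase that degrades inflammatory mRNAs, went from 3.39 ± 0.106 to 37.8 ± 4 FPKM (3.14, SE 0.13). Rel reached 7.69 ± 0.301 FPKM (1.39, SE 0.09), Relb rose by 2.16 and Nfkb1 by 0.57. Fos (-2.16, from the same uneven unstimulated levels) and the insulin signalling gene Irs1 (-0.78) fell. Limma called 190 genes, 159 higher and 31 lower, 71 by at least 2-fold. Chemokine genes rose in 11 of 15 cases and inhibitor genes in 7 of 11 (11 and 7 adjusted over the list alone), and immediate-early genes in 7 of 20, where 2 fell (11 and 2 adjusted over the list alone).

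After 3 h with IL-1β, Cxcl5 reached 358 ± 61.3 FPKM (5.90, SE 0.23), while Cxcl1 stood at 288 ± 23.2 (4.92) and Nfkbia at 103 ± 10.1 (1.73). The metallothionein gene Mt2 went from 2.78 ± 0.322 to 40 ± 17.1 FPKM (3.34), and Lcn2, an iron-binding defence protein, reached 15 ± 4.33 (2.44). Relb (2.25) and Nfkb1 (1.07) were higher than in unstimulated cells, and Rel (0.21, adjusted p = 0.288) was not called. Egr1 (-2.39) and the vasoconstrictor gene Edn1 (-1.72) fell. Limma called 440 genes, 245 higher and 195 lower, 79 by at least 2-fold. Of 15 chemokine genes 10 rose and 0 fell (13 and 0 adjusted over the list alone; adjusted p = 3.1e-40; 3.5e-10 with an estimated correlation), and of 20 immediate-early genes 3 rose and 6 fell (4 and 7 adjusted over the list alone; adjusted p = 0.0111, and adjusted p = 0.264 with an estimated correlation). Interferon-stimulated genes rose in 2 of 15 cases (3, with 1 that fell, adjusted over the list alone; adjusted p = 0.0228; adjusted p = 0.224 with an estimated correlation).

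Averaged over the 4 temperatures, some chemokine and feedback genes stood higher with TNF-α and others with IL-1β. After 1 h Ccl20 (1.12), Tnfaip3 (0.92, SE 0.05), Csf2 (0.80) and Nfkbia (0.60) were higher with TNF-α. With IL-1β, Zc3h12a (-1.21, SE 0.06), Cxcl1 (-1.09), Cxcl5 (-1.08) and the transcription factor gene Cebpd (-0.91) were higher. At 37 °C, Cebpd stood at 40.3 ± 4.94 FPKM with IL-1β and 15.7 ± 1.71 with TNF-α. The average hides a reversal of Cxcl1 at 24 °C. There its libraries stood at 94.4 to 118 FPKM after 1 h with TNF-α and at 67.1 to 79.0 with IL-1β. After 3 h the TNF-α side was led by Ccl5 (2.87, SE 0.18), Csf2 (2.69), Cxcl2 (2.15) and the interferon-induced chemokine Cxcl10 (2.04), and the IL-1β side by Cxcl5 (-2.17, SE 0.11), Cebpd (-1.56), Zc3h12a (-1.49) and Lcn2 (-1.38). Rel did not pass the test at 1 h (0.07, adjusted p = 0.899) and was higher with TNF-α at 3 h (0.43, SE 0.05, adjusted p = 1.8e-09). Limma called 53 genes at 1 h, 42 higher with TNF-α and 11 with IL-1β, and 969 at 3 h, 487 and 482 (589 and 344 after rescaling). At 3 h, 7 of 15 interferon-stimulated genes were higher with TNF-α and 0 with IL-1β (7 and 0 adjusted over the list alone; adjusted p = 1.3e-11; 0.000146 with an estimated correlation). Immediate-early genes were higher with TNF-α in 12 of 20 cases and with IL-1β in 1 (13 and 2 adjusted over the list alone; 12 and 0 after rescaling). Chemokine genes were higher with TNF-α in 10 of 15 cases and with IL-1β in 3 (10 and 3 adjusted over the list alone).

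At 34 °C the cytokines raised chemokine, feedback and subunit genes as well. TNF-α raised Cxcl1 by 5.10, Tnfaip3 by 5.04, Ccl2 by 4.89 and Rel by 1.19 (SE 0.09) after 1 h, and Icam1 (92.9 ± 9.08 FPKM, 5.43) and Ccl5 (18.3 ± 3.21 FPKM, 3.94) after 3 h, when Relb stood at 3.43 and Rel at 0.74. IL-1β brought Cxcl1 to 619 ± 46.5 FPKM after 1 h (6.31), with Rel at 1.09, and Cxcl1 was still 5.72 above unstimulated cells after 3 h. Limma called 174 genes (153 higher, 21 lower) and 1272 (578 and 694; 726 and 512 after rescaling) for TNF-α at 1 and 3 h. For IL-1β it called 117 (112 and 5) and 534 (269 and 265). Chemokine genes rose in 10 of 15 cases (TNF-α, 1 h), 12 (TNF-α, 3 h, where 1 fell), 9 (IL-1β, 1 h) and 10 (IL-1β, 3 h), or 11, 12, 10 and 11 adjusted over the list alone. After 3 h with TNF-α, 7 of 15 interferon-stimulated genes rose (7 adjusted over the list alone), and clock genes rose in 1 of 15 cases and fell in 6 (1 and 6 adjusted over the list alone).

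At 40 °C many chemokine genes rose with the cytokines, and some heat shock genes fell from their unstimulated level. TNF-α raised Ccl2 by 5.18, Icam1 by 4.80, Relb by 3.00 and Rel by 1.37 (SE 0.09) after 1 h, and Icam1 (101 ± 12.8 FPKM, 5.68) and Ccl5 (28.3 ± 4.96 FPKM, 4.35) after 3 h. IL-1β raised Cxcl1 by 6.04 and Rel to 9.12 ± 0.791 FPKM (1.48) after 1 h; after 3 h Rel stood at 2.46 ± 0.201 FPKM (-0.07, adjusted p = 0.76). Hspa1b went from 207 ± 36.5 FPKM in unstimulated cells to 79.1 ± 13.5 after 3 h with TNF-α (-1.37) and 59.2 ± 12.7 with IL-1β (-1.79). Herpud1 went from 209 ± 48.3 to 47.7 ± 3.43 (-2.09) and 45.4 ± 6.96 (-2.16). Those cells had spent 3 h longer at 40 °C than the unstimulated ones, so hours at the temperature and the cytokine cannot be told apart here.

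Limma called 544 genes (306 higher, 238 lower; 359 and 169 after rescaling) and 1950 (1003 and 947) for TNF-α at 40 °C after 1 and 3 h, and 320 (223 and 97) and 876 (469 and 407; 418 and 463 after rescaling) for IL-1β. The first count was 374 without 40 °C TNF-α 1 h replicate 1, and the last 578 without 40 °C IL-1β 3 h replicate 3. That TNF-α library had r of 0.972 and 0.969 with the other replicates of its group, which had 0.978 with each other. Chemokine genes rose in 11, 12, 11 and 10 of 15 cases in that order, or 11, 12, 11 and 11 adjusted over the list alone. Heat shock genes fell in 5 of 22 cases after 1 h with TNF-α and in 8 after 3 h, when 1 rose, and in 4 and 8 with IL-1β; adjusted over the list alone, 5, 8, 5 and 9 fell. After 3 h with IL-1β the heat shock list had an adjusted p of 3e-06 (0.0336 with an estimated correlation), and with TNF-α 0.000545, with adjusted p = 0.131 with an estimated correlation. Also after 3 h with IL-1β, 8 of 13 hypoxia and glycolysis genes rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 5e-07; 0.00226 with an estimated correlation), Hk2 by 1.39 among those that rose.

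At 24 °C, TNF-α raised few genes after 1 h and more after 3 h. After 1 h Cxcl1 rose to 109 ± 13.1 from 30 ± 6.05 FPKM (1.85, SE 0.24), Nfkbia to 62 ± 3.13 from 32.6 ± 5.73 (0.92, SE 0.13), and Zfp36 (0.92), Ier3 (0.73) and Tnfaip3 (0.62) rose. Rel, at 2.15 ± 0.332 against 1.88 ± 0.0954 FPKM (0.12, adjusted p = 0.739), and Ccl2 (0.39, adjusted p = 0.437) were not called. After 3 h Cxcl1 stood at 471 ± 34.7 FPKM (3.95), Nfkbia at 334 ± 22.8 (3.33), Tnfaip3 had risen by 3.28, Ccl2 by 2.95 and Il6 by 2.21, and Rel stood at 3.62 ± 0.384 (0.68, SE 0.09). Icam1 reached 5.07 ± 0.748 FPKM (1.64), Nfkb1 stood at 24.3 ± 2.47 (-0.19, adjusted p = 0.466), and Ccl5, listed at 0 in unstimulated cells, at 0.887 ± 0.885. The clock genes Bhlhe40 (1.58) and Per1 (21.4 ± 1.64 from 8.47 ± 1.7 FPKM, 1.25) also rose.

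Limma called 17 genes after 1 h with TNF-α at 24 °C, 12 higher and 5 lower (11 without 24 °C TNF-α 1 h replicate 3, and 34 in another split of the same libraries). After 3 h it called 245, 139 higher and 106 lower (163 and 72 after rescaling), and 162 without 24 °C unstimulated replicate 1. Immediate-early genes rose in 2 of 20 cases at 1 h (11 adjusted over the list alone; adjusted p = 3.7e-14; 0.000333 with an estimated correlation) and in 7 at 3 h (13 adjusted over the list alone). Chemokine genes rose in 2 of 15 cases at 1 h (2 adjusted over the list alone) and in 9 at 3 h (11 adjusted over the list alone; adjusted p = 6.5e-32; 4.3e-09 with an estimated correlation), and clock genes in 4 of 15 at 3 h (6 adjusted over the list alone).

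For IL-1β at 24 °C, 5 genes were called after 1 h in limma (6 in another split of the same libraries). Gadd45b, a stress gene, rose by 0.67 (SE 0.09, adjusted p = 2e-05), Cxcl1 by 1.27, Hk2 by 0.61 and Ier3 by 0.49, and Psrc1, a mitotic spindle gene, fell by 0.43. Gadd45b and Psrc1 lie outside the naming rule and were chosen after the values were seen. The count was 1 without 24 °C IL-1β 1 h replicate 2, 10 without 24 °C unstimulated replicate 3 and 11 without 24 °C IL-1β 1 h replicate 3. Cxcl1 was not called without 24 °C unstimulated replicate 1 (1.10, adjusted p = 0.154) or without 24 °C IL-1β 1 h replicate 2 (1.21, adjusted p = 0.0751). Nor was Ier3 without 24 °C unstimulated replicate 2 (0.47, adjusted p = 0.0508) or IL-1β 1 h replicate 2 (0.49, adjusted p = 0.0543), nor Hk2 without unstimulated replicate 1 or 3 or IL-1β 1 h replicate 2 or 3 (0.55 to 0.58). After 3 h Cxcl1 reached 378 ± 25.8 FPKM (3.63), Nfkbia 224 ± 9.46 (2.75), Tnfaip3 59.4 ± 1.85 (2.28) and Rel rose by 0.55 (SE 0.09). Limma then called 144 genes, 93 higher and 51 lower. Of 15 chemokine genes 6 rose and 0 fell (8 and 0 adjusted over the list alone; adjusted p = 9.8e-22; 3.3e-07 with an estimated correlation), with 4 of 11 inhibitor genes and 4 of 15 clock genes (5 and 5 adjusted over the list alone).

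**Figure D2:**
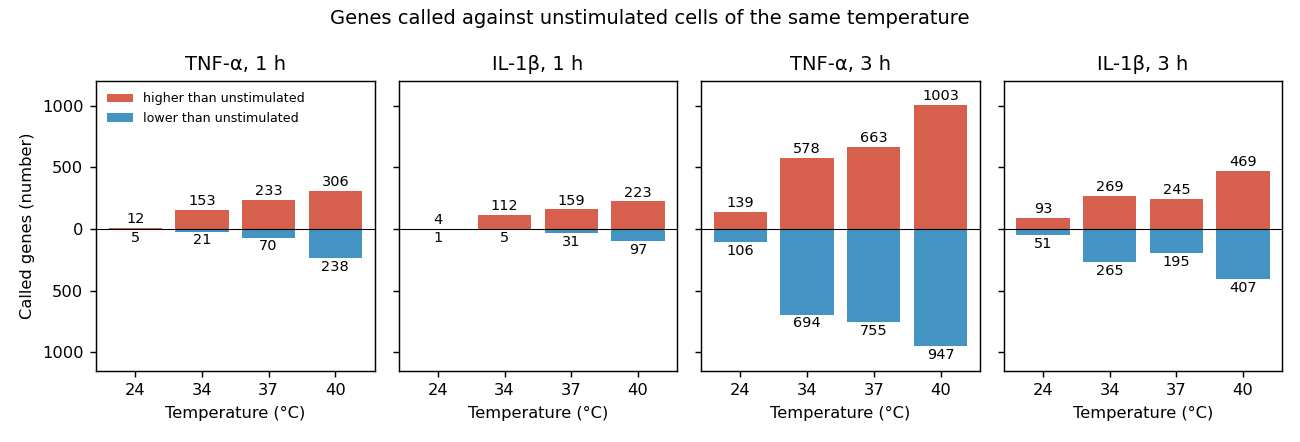
Genes called in limma as higher (upward) or lower (downward) than unstimulated cells of the same temperature, for each cytokine, time and temperature, with 3 libraries per group. TNF-α at 3 h gave 245 genes at 24 °C and 1950 at 40 °C.

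**Figure D3:**
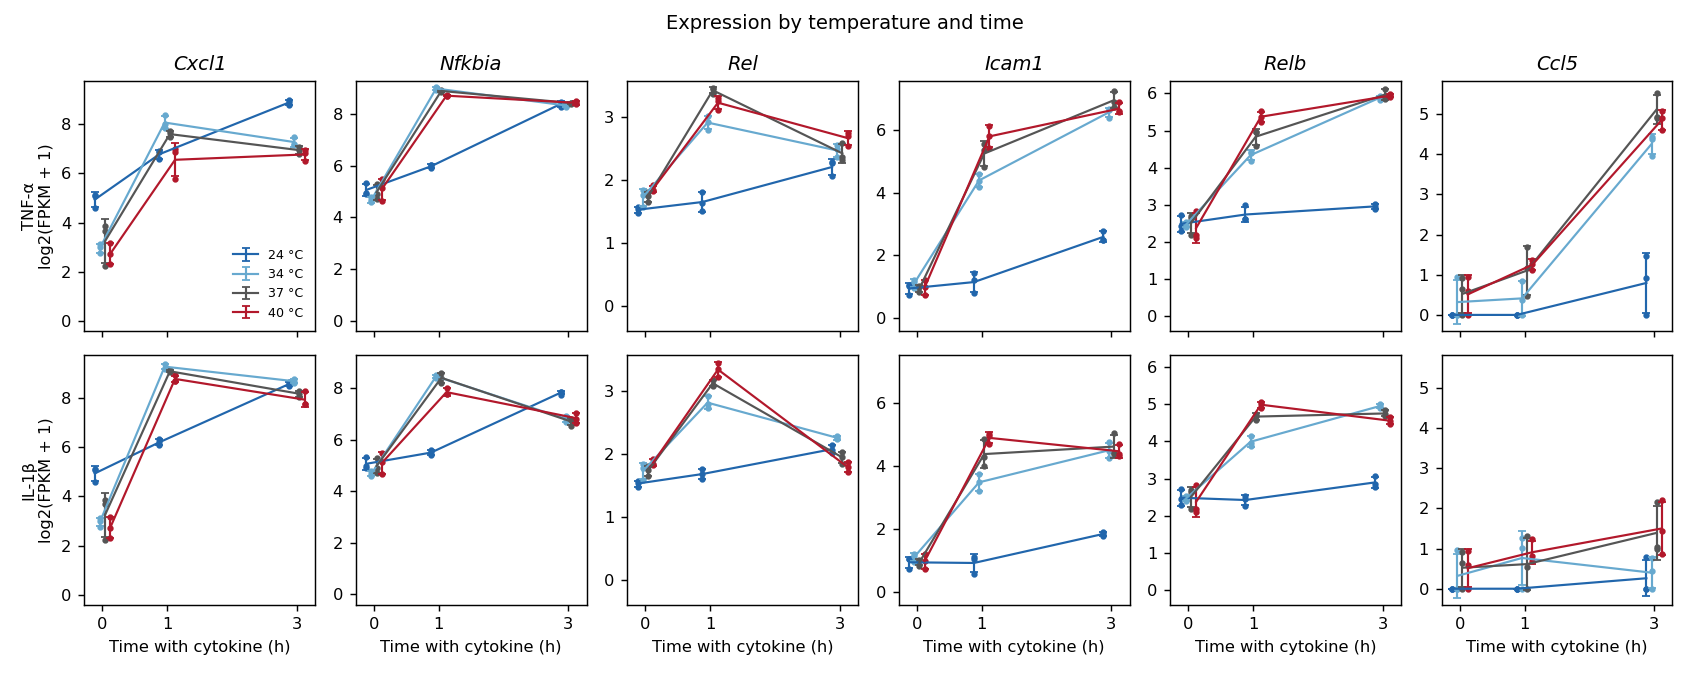
Expression as log2(FPKM + 1) against hours with TNF-α (upper panels) or IL-1β (lower panels) at 4 temperatures, with mean ± SD and 3 libraries per point. At 24 °C after 3 h with TNF-α, Nfkbia stood at 334 ± 22.8 FPKM (343 ± 4.92 at 37 °C) and Relb at 6.77 ± 0.346 (61.8 ± 6.27 at 37 °C).

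The test of the difference between the responses at 24 and 37 °C was past its threshold for some genes at 1 h alone and for others also, or only, at 3 h. After 1 h with TNF-α the smaller responses at 24 °C were those of Ccl2 (-5.00, SE 0.24, adjusted p = 4.9e-21), Csf2 (-4.22), Icam1 (-4.08), Tnfaip3 (-4.07), Nfkbia (-3.00), Relb (-2.08) and Rel (-1.57, SE 0.13, adjusted p = 3.8e-12). After 3 h no difference was called for Rel (-0.01, adjusted p = 0.984), Nfkbia (-0.13, adjusted p = 0.779), Tnfaip3 (-0.33, adjusted p = 0.205) or Cxcl1 (0.25, adjusted p = 0.772). The differences that stood at 3 h were those of Icam1 (-4.34, SE 0.29), Gbp2 (-3.89), the chemokine genes Cxcl16 (-3.84) and Ccl5 (-3.80, SE 0.52), Relb (-2.99, SE 0.19), Ccl2 (-2.91) and Nfkb1 (-1.90, SE 0.15). Among positive differences were Fos (2.88), Adamts1 (2.42, SE 0.18), Egr1 (2.29) and Per1 (2.04, SE 0.15), 4 genes that at 37 °C were lower after 3 h with TNF-α than in unstimulated cells. The stimulated cells had also spent 3 h longer at 37 °C, so the cytokine and the hours cannot be told apart for these falls. Since Cxcl1 and Ccl2 started higher at 24 °C, part of their smaller response lies in the unstimulated cells.

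Limma called 172 genes for that difference at 1 h, 37 positive and 135 negative, and 802 at 3 h, 387 and 415. A positive difference can be a fall at 37 °C that was weaker or absent at 24 °C. After 3 h with TNF-α, 755 genes were called lower at 37 °C and 106 at 24 °C. Responses were smaller in 10 of 15 chemokine genes (12 adjusted over the list alone; adjusted p = 1.6e-36; 8.6e-10 with an estimated correlation), 7 of 11 inhibitor genes (8 adjusted over the list alone) and 3 of 3 subunit genes (3 adjusted over the list alone) at 1 h. At 3 h they were smaller in 9 chemokine genes and larger in 1 (9 and 2 adjusted over the list alone), smaller in 6 of 10 adhesion and effector genes and larger in 1 (6 and 1 adjusted over the list alone), and smaller in 6 of 15 interferon-stimulated genes (7 adjusted over the list alone; adjusted p = 2.7e-06; 0.00733 with an estimated correlation). Immediate-early genes went the other way at 3 h, larger in 7 of 20 cases and smaller in 1 (9 and 1 adjusted over the list alone; adjusted p = 2.2e-06; 0.0252 with an estimated correlation), and clock genes were larger in 5 of 15 (7 adjusted over the list alone; adjusted p = 7.7e-06; 0.000143 with an estimated correlation).

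For IL-1β the feedback gene Tnfaip3 had the smaller response at 24 °C after 1 h and the larger one after 3 h. After 1 h the differences were -4.56 for Cxcl1 (SE 0.34), -4.48 for Ccl2, -3.35 for Tnfaip3, -2.98 for Nfkbia and -1.24 for Rel (SE 0.13, adjusted p = 5.6e-09). After 3 h they were 1.11 for Tnfaip3 (SE 0.15, adjusted p = 1.6e-06; 59.4 ± 1.85 FPKM at 24 °C against 17.3 ± 4.25 at 37 °C), 2.03 for the transcription factor gene Irf1, 1.86 for Zfp36 and 2.76 for Egr1. Cxcl5 (8.94 ± 2.55 against 358 ± 61.3 FPKM; -4.94, SE 0.32), Icam1 (-2.77), Lcn2 (-2.32) and Relb (-1.84, SE 0.19) had smaller responses, and for Rel no difference was called (0.34, adjusted p = 0.227). Limma called 85 genes at 1 h, 10 with a positive and 75 with a negative difference, and 231 at 3 h, 107 and 124 (114 and 113 after rescaling). At 1 h the responses were smaller in 10 of 15 chemokine genes, 5 of 11 inhibitor genes and 3 of 3 subunit genes (10, 6 and 3 adjusted over the list alone). At 3 h they were smaller in 7 chemokine genes (8, with 1 larger, adjusted over the list alone), and larger in 2 and smaller in 3 inhibitor genes (2 and 5 adjusted over the list alone; adjusted p = 0.0381; adjusted p = 0.116 with an estimated correlation), and larger in 6 immediate-early genes (10 adjusted over the list alone; adjusted p = 5.9e-14; 0.000363 with an estimated correlation).

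Between 34 and 37 °C the responses differed in a handful of immediate-early genes. At 1 h the differences were positive for Egr1 (2.88 with TNF-α, SE 0.43, and 2.54 with IL-1β), Btg2 (1.45 and 1.43), Zfp36 (1.32 and 1.40) and Ier3 (0.60 and 0.60). The rise of Atf3 with TNF-α was smaller at 34 °C (-1.35). From 48.2% (Ier3) to 87.1% (Zfp36) of the positive TNF-α differences lay in the unstimulated libraries (closing section). Fos also had positive differences (2.55 and 2.36), but it fell at 37 °C (-1.92 and -2.16) and was not called at 34 °C (0.62, adjusted p = 0.728, and 0.20, adjusted p = 1). These are all the genes limma called: 6 for TNF-α (5 positive, 1 negative) and 5 for IL-1β (5 and 0). Zfp36 with TNF-α and Ier3 lie outside the naming rule, were chosen after the values were seen, and were followed gene by gene only without the unstimulated libraries at 37 °C (closing section). At 3 h limma called 0 genes for TNF-α, with 532 at an unadjusted p under 0.05, and 0 for IL-1β, with 480. With the replicate number as a block it called 9 and 6. As a list, immediate-early genes had higher responses at 34 °C at 1 h with TNF-α (5 positive and 1 negative; 7 and 3 adjusted over the list alone; adjusted p = 1.1e-07; 0.0115 with an estimated correlation). The 3 subunit genes rose less at 34 °C as a list with TNF-α at 1 h (median -0.45, 0 called over all genes, 3 smaller adjusted over the list alone; adjusted p = 1.3e-06; 0.000345 with an estimated correlation) and with IL-1β (median -0.52, 0 called over all genes, 3 smaller adjusted over the list alone; adjusted p = 3.7e-07; 0.000184 with an estimated correlation). Rel itself was at -0.51 (adjusted p = 0.338) and -0.30 (adjusted p = 1).

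Most of these 34 °C counts depended on single libraries. For TNF-α at 1 h limma called 3 genes without 37 °C unstimulated replicate 1 or 2, 34 °C unstimulated replicate 2 or 34 °C TNF-α 1 h replicate 2 or 3. For IL-1β at 1 h it called 3 without 37 °C unstimulated replicate 1 or 2, 37 °C IL-1β 1 h replicate 1 or 2, 34 °C unstimulated replicate 2 or 34 °C IL-1β 1 h replicate 3. For TNF-α at 3 h it called 2 without 34 °C unstimulated replicate 1 and 3 without 37 °C unstimulated replicate 3, and for IL-1β at 3 h 2 without 37 °C IL-1β 3 h replicate 1, 1 without 34 °C unstimulated replicate 3 and 4 without 37 °C unstimulated replicate 3. The Fos call with TNF-α ended (2.21 to 2.55) without replicate 1 or 2 of 34 °C unstimulated, 37 °C unstimulated or 37 °C TNF-α 1 h, or replicate 2 or 3 of 34 °C TNF-α 1 h. With IL-1β it ended (1.96 to 2.46) without replicate 1 or 2 of 34 °C unstimulated, 37 °C unstimulated or 37 °C IL-1β 1 h, or replicate 2 or 3 of 34 °C IL-1β 1 h. The Atf3 call ended (-1.40 to -1.23) without any replicate of 37 °C unstimulated or 34 °C TNF-α 1 h, replicate 2 or 3 of 34 °C unstimulated, or replicate 1 or 3 of 37 °C TNF-α 1 h. Egr1 and Btg2 were called without each library in turn.

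Between 40 and 37 °C the called differences included several stress genes. No NF-κB subunit gene was called over all genes, while adjusted over the list alone 2 had a larger and 1 a smaller response to TNF-α at 1 h. Gdf15, a stress-induced cytokine gene, stood at 61.7 ± 5.29 FPKM in unstimulated cells at 40 °C and 48.1 ± 5.49 after 1 h with TNF-α, against 25.2 ± 7.14 and 64.7 ± 13.4 at 37 °C (-1.69, SE 0.22; -1.61 with IL-1β). After 3 h with TNF-α the differences were negative for Herpud1 (-2.52, SE 0.29, adjusted p = 1.5e-07), Atf3 (-1.82), Hspa1b (-1.67, SE 0.17) and Chac1 (-1.61). They were positive for Egr1 (3.36, SE 0.43) and Fhod1, an actin regulator (0.82). Herpud1 and Hspa1b had fallen from their unstimulated levels at 40 °C, and their negative differences rest largely on those falls. Egr1 rose at 40 °C and fell at 37 °C, and both enter its difference. After 3 h with IL-1β the differences of Herpud1 (-2.34), Hspa1a (-1.80), Hspa1b (-1.77, SE 0.17) and Atf3 (-1.67) were again negative, and that of Hk2 was positive after 1 h (1.06). Rel was at -0.33 (adjusted p = 0.656) and 0.11 (adjusted p = 0.861) with TNF-α at 1 and 3 h, and at 0.09 and -0.28 (adjusted p = 0.698) with IL-1β.

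Limma called 14 genes for TNF-α at 1 h (2 positive, 12 negative), 31 at 3 h (10 and 21, or 8 and 31 after rescaling), and 13 (2 and 11) and 19 (2 and 17) for IL-1β. The first count was 7 without 37 °C unstimulated replicate 1 and 9 without 37 °C TNF-α 1 h replicate 2, and the IL-1β 1 h count was 6 without 40 °C unstimulated replicate 1. Heat shock genes had negative differences in 4 of 22 cases (TNF-α, 1 h), 6 (TNF-α, 3 h), 3 (IL-1β, 1 h) and 6 (IL-1β, 3 h), or 5, 7, 4 and 6 adjusted over the list alone. Camera gave adjusted p = 7.8e-05, 9.3e-11, 4.2e-05 and 4.1e-12, and adjusted p = 0.0757, 0.00267, 0.0661 and 0.00131 with an estimated correlation. Unfolded protein response genes had negative differences in 3, 3, 3 and 4 of 20 cases (4, 8, 4 and 8 adjusted over the list alone). Camera gave adjusted p = 3.6e-08 for TNF-α at 3 h (0.00798 with an estimated correlation) and 4e-08 for IL-1β at 3 h (0.00817 with an estimated correlation). Unstimulated levels of Hspa1b and Herpud1 were already higher at 40 than at 37 °C, and both levels enter these differences. That of Egr1 was lower at 40 °C (9.32 against 49.9 FPKM at 37 °C), so part of its positive difference lies in the unstimulated cells. At 37 °C it stood at 63.8, 68.9 and 17.2 FPKM in the 3 unstimulated libraries.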

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

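The results here are differences between temperatures in the response to a cytokine, each picked out because the planned test of that difference was past its threshold; the tests of explanations and the splits of the libraries were chosen only after those results were seen. Against 37 °C, limma called 172 genes (TNF-α, 1 h), 802 (TNF-α, 3 h), 85 (IL-1β, 1 h) and 231 (IL-1β, 3 h) at 24 °C. At 34 °C it called 6 (TNF-α, 1 h) and 5 (IL-1β, 1 h), and at 40 °C 14, 31, 13 and 19 in the same order as at 24 °C.

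At 24 °C the responses of early genes were smaller at 1 h and those of late genes at 1 and 3 h, with classes set on the 34 °C libraries. Early genes had risen at least 2-fold by 1 h and no further by 3 h, and late genes were at least 2-fold up at 3 h with less than 50% of that log2 rise at 1 h. For TNF-α the 42 early genes had median differences from 37 °C of -1.39 at 1 h and 0.068 at 3 h (quartiles -0.20 to 0.56), and the 73 late genes -0.57 (beside a median response of 0.55 at 37 °C) and -1.45 (quartiles -1.98 to -1.17; 62 called smaller). For IL-1β the 39 early genes had -1.24 and 0.39 and the 25 late genes -0.52 (beside 0.54) and -1.22. Early genes had already fallen back at 37 °C by 3 h (TNF-α, 1.55 to 0.87), so the 3 h values leave open whether they were held up as much as late genes. Lower depth of the 24 °C libraries was argued against as the whole cause for late genes, since the 32 late TNF-α genes with at least 20 FPKM at 34 °C had a median difference of -1.39 at 3 h (upper quartile -1.12). A plain delay, with 3 h at 24 °C standing where 1 h at 37 °C stood, was argued against as the whole cause for early IL-1β genes (first minus second -0.74, quartiles -1.22 to -0.40). The quartiles also lay below 0 for late TNF-α genes (-0.45, quartiles -0.80 to -0.22), early TNF-α genes (-0.63, -1.01 to -0.12) and late IL-1β genes (-0.42, -0.76 to -0.19). Their upper quartiles missed the bar of this test, which was set after the values were seen. Late genes hardly rose by 3 h at 24 °C, with medians of 0.062 for TNF-α (quartiles -0.066 to 0.32) and 0.12 for IL-1β (-0.008 to 0.35). At 37 °C and 1 h their medians were 0.55 and 0.54. These values argue against such a delay as the whole cause for most late genes. It stays open for early TNF-α genes, and a longer delay was not tested. If the 24 °C libraries, numbered apart from the others, were made apart, that cannot be told apart from the temperature, and a biological cause was not tested.

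Single-gene differences at 24 °C with TNF-α at 1 h were -5.00 for Ccl2, -2.50 for Cxcl1, -1.84 for Il6, -0.73 for Nfkb1, -3.00 for Nfkbia, -1.57 for Rel, -2.08 for Relb and -4.07 for Tnfaip3. With TNF-α at 3 h they were -2.91 for Ccl2, 1.22 for Cirbp, -1.90 for Nfkb1 and -2.99 for Relb; the Cirbp call ended without 37 °C unstimulated replicate 1 (1.06, adjusted p = 0.0505). With IL-1β at 1 h they were -4.48 for Ccl2, -4.56 for Cxcl1, -1.74 for Il6, -0.66 for Nfkb1, -2.98 for Nfkbia, -1.24 for Rel, -2.23 for Relb and -3.35 for Tnfaip3. The Nfkb1 call ended without 37 °C IL-1β 1 h replicate 1 (-0.55, adjusted p = 0.101) and without 24 °C unstimulated replicate 1 (-0.62, adjusted p = 0.0511). With IL-1β at 3 h they were -2.01 for Ccl2, -1.29 for Cxcl1, -1.18 for Nfkb1, 1.02 for Nfkbia, -1.84 for Relb and 1.11 for Tnfaip3. Cxcl1 itself stood higher after 3 h with IL-1β at 24 °C (354 to 405 FPKM) than at 37 °C (264 to 310). Its negative difference thus lies in the higher unstimulated level at 24 °C. The Cxcl1 call ended without 37 °C IL-1β 3 h replicate 1 (-1.28) or 3 (-1.23), 37 °C unstimulated replicate 3 (-0.77), 24 °C IL-1β 3 h replicate 1 (-1.24) or 2 (-1.28), or 24 °C unstimulated replicate 2 (-1.19) or 3 (-1.21).

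At 34 °C the positive differences of Egr1, Btg2, Zfp36, Ier3 and Fos at 1 h (for Fos, a fall at 37 °C that was not called at 34 °C) were weighed against the state of the unstimulated cells. A median of 70.2% of the TNF-α difference lay in the unstimulated libraries (48.2% for Ier3, 68.0% for Egr1, 70.2% for Fos, 86.0% for Btg2, 87.1% for Zfp36). A different starting level alone and a different response at 34 °C cannot be told apart on these shares. With each of the 3 unstimulated libraries at 37 °C left out in turn, all 5 TNF-α differences stayed more than 2 SE above 0. The genes were chosen by that same difference. Replicates 1 and 2 stood above replicate 3 for Egr1 (63.8, 68.9 and 17.2 FPKM), Fos (35.2, 24.7 and 11.6), Btg2 (36.2, 43.5 and 20.8) and Zfp36 (13.9, 12.2 and 8.31), less clearly for Ier3 (90.0, 106 and 88.9). Each refit thus kept a high library. The values argue against 1 unusual unstimulated library at 37 °C as the whole cause. That 2 were unusual together was not tested. Egr1 (2.54 to 3.51), Btg2 (1.24 to 1.75) and Zfp36 (1.18 to 1.52) also stayed called. The calls of Fos and Ier3 ended in 2 of the 3 refits, where the highest adjusted p values were 0.159 and 0.230: at the lowest, Fos went from 2.55 (SE 0.50) to 2.21 (SE 0.51) and Ier3 from 0.60 (SE 0.13) to 0.52 (SE 0.13), smaller differences with an SE about as wide. A disturbance of the 37 °C cells by handling is a candidate cause that was not tested, and unstimulated cells kept for 1 and 3 h longer would test it.

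At 40 °C the differences were -1.52 for Hspa1a and -0.84 for Hspa1b with TNF-α at 1 h, and -1.53 and -1.67 at 3 h. With IL-1β they were -1.41 for Hspa1a, -0.81 for Hspa1b and -0.74 for Tnfaip3 at 1 h, and -1.80 for Hspa1a and -1.77 for Hspa1b at 3 h. Of these 5 calls at 1 h, 4 ended without single libraries. For Hspa1b with TNF-α these were 37 °C unstimulated replicate 1 (-0.82) or 3 (-0.81), 40 °C unstimulated replicate 3 (-0.70) and 40 °C TNF-α 1 h replicate 3 (-0.75). For Hspa1a with IL-1β they were 40 °C unstimulated replicate 1 (-1.39) or 3 (-1.25), 40 °C IL-1β 1 h replicate 2 (-1.25) and 37 °C IL-1β 1 h replicate 3 (-1.31). For Hspa1b with IL-1β they were 37 °C unstimulated replicate 1 (-0.79) or 3 (-0.77), 37 °C IL-1β 1 h replicate 1 (-0.77) or 2 (-0.79), 40 °C unstimulated replicate 1 (-0.84) or 3 (-0.67) and 40 °C IL-1β 1 h replicate 2 (-0.81) or 3 (-0.69). For Tnfaip3 with IL-1β they were 40 °C unstimulated replicate 1 (-0.74) or 3 (-0.65), 40 °C IL-1β 1 h replicate 1 (-0.68) and 37 °C IL-1β 1 h replicate 3 (-0.65).

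Other splits of the libraries were counted for these differences after the mean temperature difference of the 4 groups had been removed, with 100 of 200 possible splits for each. At 24 °C the real split was the only 1 of the 100 to call as many genes in each case: 172 against at most 56, 802 against 221, 85 against 28 and 231 against 43. A chance division of the libraries thus seldom called as many, with splits that took no account of replicate numbers. The same held at 40 °C, with 14 against 9, 31 against 3, 13 against 3 and 19 against 3, and at 34 °C for 1 h, with 6 against 3 and 5 against 3. Leaving out 1 library took the 14 to as few as 7, and the 6 and the 5 to as few as 3, no more than the highest other split. At 34 °C and 3 h the real count was 0 in limma (532 and 480 genes at an unadjusted p under 0.05), and 100 of 100 splits gave as many, at most 1 and 2. With labels exchanged and the temperature difference left in, 10 of 100 splits at 24 °C gave as many for each of the 4, up to 2387, 2221, 1882 and 2082 genes, since the exchange of labels in 1 arm then counts the temperature difference itself. That structure gave up to 154, 308, 136 and 260 genes at 34 °C (7, 100, 9 and 100 splits as large) and up to 1130, 1164, 1047 and 1047 at 40 °C (14, 12, 15 and 13 splits as large).

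For TNF-α against IL-1β over the 4 temperatures, 1 of 100 drawn splits of 80000, the real one, was as large: 53 genes against at most 3 at 1 h and 969 against 126 at 3 h. A chance division thus seldom called as many here. Comparisons of 3 with 3 libraries have 10 splits, too few for a share under 0.05. Their real count and highest other were 2098 and 1 (24 °C unstimulated), 37 and 2 (34 °C) and 419 and 3 (40 °C). For the responses to TNF-α at 1 h they were 17 and 34 at 24 °C, where 2 of the 10 splits were as large, 174 and 2 at 34 °C, 303 and 1 at 37 °C and 544 and 17 at 40 °C. To TNF-α at 3 h they were 245 and 17, 1272 and 1, 1418 and 0, and 1950 and 1. To IL-1β at 1 h they were 5 and 6 at 24 °C, where 2 splits were as large, 117 and 1, 190 and 0, and 320 and 0. To IL-1β at 3 h they were 144 and 12, 534 and 1, 440 and 2, and 876 and 0.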

How the results depend on the processing

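The mean-FPKM filter and the model of 34, 37 and 40 °C alone were chosen only after the results were seen. No called gene changed sign under rescaling, the pseudocount, the block or the added settings. Rescaling turned the balance of higher and lower genes at 24 °C unstimulated (956 and 1142 to 1095 and 1021), and TNF-α at 3 h and 34 °C (578 and 694 to 726 and 512) and 37 °C (663 and 755 to 810 and 610). It also did so for IL-1β at 3 h and 40 °C (469 and 407 to 418 and 463) and IL-1β at 3 h, 24 against 37 °C (107 and 124 to 114 and 113). With the replicate number as a block, limma called 35 genes (17 without it) for TNF-α at 1 h and 24 °C and 246 (144) for IL-1β at 3 h and 24 °C. Differences against 37 °C with the block were 264 (172) for TNF-α at 1 h and 385 (231) for IL-1β at 3 h at 24 °C, 9 (0) and 6 (0) at 3 h for TNF-α and IL-1β at 34 °C, and 24 (14), 79 (31), 27 (13) and 40 (19) at 40 °C. The labels give the numbers no shared day or batch. At 34, 37 and 40 °C, replicates 1, 2 and 3 carry the library numbers 1 to 15, 16 to 30 and 31 to 45. Of pairs with the same number, 39 of 315 had residual correlations above 0.1 at 34, 37 and 40 °C and 4 of 30 at 24 °C, a bar that a weak shared shift need not reach. On average, 45 of 45 libraries at 34, 37 and 40 °C and 10 of 15 at 24 °C were closest to their own number (mean r 0.0556 against -0.0278, and 0.0293 against -0.0145). Libraries of the same number were thus weakly related, most clearly at 34, 37 and 40 °C. The main counts leave this structure out. A pseudocount of 0.1 gave 11 genes (5) for IL-1β at 1 h and 24 °C, and rescaling gave 3 (5) for IL-1β at 1 h, 34 against 37 °C. The filter at an FPKM of 1 in 3 libraries removed no gene, so the alternative without a filter changes nothing and gave no value; a mean FPKM of at least 1 kept 8927 genes, and all 33 counts stayed within 1.5 times. In the model of 34, 37 and 40 °C alone, 22 of 22 counts did so.

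Leaving out 1 library in turn gave 276 counts within 1.5 times and 30 beyond. The ranges were 14 to 28 for 34 °C and 242 to 400 for 40 °C unstimulated cells, 11 to 21 (TNF-α, 1 h), 162 to 213 (TNF-α, 3 h) and 1 to 11 (IL-1β, 1 h) for responses at 24 °C, and 578 to 727 for IL-1β at 3 h and 40 °C. For differences against 37 °C they were 3 to 6, 0 to 3, 3 to 6 and 0 to 4 at 34 °C (TNF-α 1 h, TNF-α 3 h, IL-1β 1 h, IL-1β 3 h), and 7 to 21 (TNF-α, 1 h) and 6 to 17 (IL-1β, 1 h) at 40 °C. Of 939 calls of named genes, 209 were lost without some 1 library. Rescaling ended 11 calls and added 3, the pseudocount ended 20, and the block ended 2 and added 9. The model of 34, 37 and 40 °C alone ended 35. In it, 3 of the 6 genes called for TNF-α and 3 of the 5 for IL-1β at 1 h, 34 against 37 °C, stayed called. Among 561 list tests, the estimated correlation ended 75 calls, and rescaling ended 7 and added 2.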

Other observations

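Between unstimulated cells and those with TNF-α for 3 h, levels of the clock gene Per1 moved in opposite directions at 37 and 24 °C. Per1, a core clock repressor, went from 13.5 ± 1.6 to 7.41 ± 0.82 FPKM with TNF-α at 3 h and 37 °C, and from 8.47 ± 1.7 to 21.4 ± 1.64 at 24 °C (mean ± SD, n = 3; difference of the responses 2.04). As a list, clock genes rose at 24 °C after 3 h with TNF-α (4 of 15, 0 fell, camera adjusted p = 1.1e-10, and 4.9e-07 with an estimated correlation). By count of called genes, 6 of 15 fell and 1 rose at 34 and at 40 °C. Some clock genes also rose at 24 °C after 3 h with IL-1β. The stimulated cells had spent 3 h longer at their temperature, so the cytokine and the hours cannot be told apart for these changes. Il6, an interleukin with effects on fever and the acute phase, reached 53.8 ± 7.18 FPKM at 34 °C and 14.6 ± 4.69 at 40 °C after 1 h with TNF-α, levels that were not tested against each other.

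Among mitochondrial genes the rise at 24 °C was uneven, and the tests in this paragraph were chosen after it was seen. Lars2, a mitochondrial tRNA synthetase gene, stood at 270 ± 109 FPKM in unstimulated cells at 24 °C and 27.1 ± 5.3 at 37 °C (log2 change 3.21, SE 0.50), with mt-Rnr1 at 2.60 and mt-Rnr2 at 2.64 (SE 0.50 each). Among mitochondrial mRNAs, mt-Nd2 (2.02, SE 0.35, above every other library in 15 of the 15 libraries at 24 °C), mt-Nd1 (0.87, SE 0.22) and mt-Nd5 (0.87) were also called, mt-Nd5 not without 24 °C unstimulated replicate 2 (0.62) or 3 (0.73). A rise of all mitochondrial transcripts was argued against by mt-Co1, the most abundant mitochondrial mRNA measured (-0.037, SE 0.20). Ribosomal RNA reads that entered the 24 °C libraries in unequal amounts may be the cause for Lars2 and the ribosomal RNAs. Whether they bear on the mitochondrial mRNAs was not tested. Over the 15 libraries at 24 °C, Lars2 followed mt-Rnr1 as deviations from group means (Pearson r = 0.95, permutation p = 0.00015, Spearman 0.964, and Pearson r = 0.895 without the 2 farthest libraries). Within groups, mt-Rnr1 varied 1.86- to 7.35-fold. Temperature and a separate making of these libraries, which their run of numbers leaves possible, cannot be told apart here: 14 of the 15 libraries at 24 °C had Lars2 above every library at the other temperatures, and no other library shares that run.

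7SL RNA, the RNA of the signal recognition particle, held a large share of the FPKM sum, which weighs short transcripts up and is not a share of the fragments. It held 43.6 ± 1.38% of the FPKM sum at 24 °C, 38.1 ± 0.845% at 34 °C, 39.1 ± 0.932% at 37 °C and 42.0 ± 2.04% at 40 °C (mean ± SD, n = 15 each).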
